A study of Mus musculus with 12 samples.

How the data were processed

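The series measured messenger RNA by sequencing in microglia, the resident macrophages of the brain, of mice. The sample characteristics gave postnatal days 35 to 40 as the age of the mice, and the extraction protocol gave 30 to 45. Per the labels' protocols, brains were dissociated, microglia were sorted by fluorescence and cultured under oxygen-glucose deprivation (OGD), a culture model of ischaemia in which cells lack both oxygen and glucose. OGD lasted 6 h, and cells were taken either straight after it or after a further 24 h of recovery. Control mice carried the Cx3cr1-EGFP reporter (here WT), and the knockout mice (KO) carried it together with a deletion of Slc2a5, which encodes the fructose transporter GLUT5. All 12 samples were labelled male. The titles placed 3 samples in each of 4 groups, here called WT-OGD, KO-OGD, WT-recovery and KO-recovery, with replicate numbers from the same titles. The treatment field of WT-recovery replicate 1 named OGD without recovery, while its title and library name placed it in the recovery group, and it was grouped by its title. Nothing in the labels said that replicates came from separate animals or cultures, so every p-value measured only the spread between these samples, which may be technical. No sample without OGD was analysed here. Libraries were made with a kit for stranded total RNA per the labels, although the molecule field named polyA RNA.

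The authors deposited raw read counts per gene, 1 whole-number value per gene and library, not normalized. Per the submitters' processing notes, HISAT2, featureCounts and the mouse build GRCm38 were used. Versions, the annotation release and the counting options (strand, reads matching several places, reads over 2 genes) were not given in the sources used here. For that reason, genes that overlap other annotated genes, antisense pairs and near-identical copies are reported as uncertain. The table held 55421 genes by Ensembl identifier, all of its columns of counts were used, and no entry was a total or unassigned class. Identifiers were matched to GENCODE M21 (GRCm38) for symbols and coordinates. With its version number 54673 matched, and without it 55240 did. The 181 identifiers without a symbol held at most 0.0394% of the counts of a library, and 229 shared their symbol with another.

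Total counts ranged from 9885259 to 45347118 per library. The recovery libraries were the shallower ones, so low genes had the wider error there. Intervals for genes with 1 to 3 counts in a group are exact 95% binomial intervals of the count ratio. A group at 0 was set to a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Within each group the counts of each pair of replicates were compared by chi-square over genes with at least 20 counts. The statistic per degree of freedom lay between 6.66 and 60.2, so every pair differed by more than sampling noise and each library counted as 1 sample.

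Counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16, which left 18842, and library sizes were scaled by TMM factors. A quasi-likelihood model with robust dispersions (glmQLFit) was fitted to all 12 libraries with 1 mean per group, since each group alone has 2 degrees of freedom, and no covariate. Contrasts were tested with glmQLFTest and adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p below 0.05. The common biological coefficient of variation was 0.119. The contrasts were KO against WT after OGD, KO against WT after recovery, recovery against OGD in WT, recovery against OGD in KO, the interaction (the recovery change in KO less that in WT), and both main effects averaged over the other factor. A standard error (SE) is the size of the log2 fold change divided by the root of its F statistic. Levels in CPM, counts scaled to the TMM-adjusted library size, are given as mean ± SD of 3 libraries (n = 3). The median log2 fold change of all genes lay within 0.04 of 0 in each contrast under TMM.

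Gene lists, named genes, contrasts and the first set of alternative settings were fixed before the data were examined. There were 27 lists: fructose handling, glycolysis, targets of the hypoxia factor HIF, respiratory chain subunits encoded in the mitochondrial genome and in the nucleus, inflammatory cytokines, interferon-stimulated genes, homeostatic microglia, disease-associated microglia, phagocytosis, antigen presentation, proliferation, the integrated stress and unfolded protein responses, immediate early and heat shock genes, antioxidant targets of NRF2, cholesterol synthesis, lipid efflux and storage, p53 and apoptosis, repair or alternative activation, and markers of neurons, astrocytes, the oligodendrocyte lineage, endothelial and mural cells, border macrophages, monocytes, neutrophils and lymphocytes. Slc2a5 was left out of all lists but fructose handling. Lists were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 27 lists of a contrast, and again with an estimated correlation. Members called were counted over all genes and adjusted over the list alone. Of 72 list calls, 6 held with an estimated correlation: those of the oligodendrocyte and monocyte lists in the recovery contrasts of WT, of KO and of both averaged.

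Genes were named by rule. Slc2a5 came first. Then came the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap of the libraries of both groups, leaving out unnamed gene models. Then came up to 4 called members per list by smallest p. Up to 2 members per list that did not pass may be given as values. In the averaged and interaction contrasts the highest of the 4 groups had to reach 5 CPM, and overlap was not considered. The text names fewer, from the top of each order, and some genes that met the rule are not reported here. Eno1, Pcna, Cx3cr1 and the sex-linked genes beside Xist and Tsix were chosen after their values were seen. A second astrocyte list was chosen after the fall of the first was seen and before its own values were, except for 2 genes, which were left out of its test. Shared calls were set against the number expected for independent lists, with a two-sided Fisher's exact test. Both genotype contrasts share no library, nor do both recovery contrasts. Drawings were made with matplotlib 3.10.9 in Python 3.11.15.

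The pipeline was tested on simulated counts with 200 changed genes per contrast, as many raised as lowered, at the depth of these libraries. The astrocyte list was lowered 2-fold besides. In the simulated OGD genotype contrast (18421 genes), 56.7% of 1.5-fold, 85.1% of 2-fold and 97.0% of 4-fold changes were called. In the recovery genotype contrast (18396 genes) the shares were 41.8%, 77.6% and 90.9%. For recovery in WT (18429 genes) they were 50.7%, 83.6% and 98.5%, and in KO (18384 genes) 55.2%, 74.6% and 95.5%. False calls made up 6.86%, 2.72%, 4.24% and 3.73% of the calls, in the same order. The real contrasts called far more genes, and that of genotype after OGD mostly falls, so these shares may not carry over to them.

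Alternative settings fixed in advance were DESeq2 1.42.0, RLE scaling, no low-count filter, the replicate number as a block, only the libraries compared, a test against a fold of 1.5 (glmTreat), removal of the mitochondrial and the 50 most abundant genes, each library left out in turn, an unadjusted p below 0.01 for the overlap of calls, and a mean of at least 10 CPM for the correlation. Chosen after seeing the data were thinning of every library to 9885259 counts, the mean log2 CPM of the astrocyte list as a covariate, removal of 984 genes on X and Y and within 10 Mb of Slc2a5 and Cx3cr1, and removal of the 2 libraries with the highest mitochondrial share. Up to 100 other splits of the samples per contrast were refitted. The permutation test of a difference of medians used 100000 resamples. Nothing was deconvolved, and isoforms were not analysed here.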

Results

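The data were gene-level read counts from 12 libraries of sorted mouse microglia, cultured for 6 h under OGD and taken either at once or after 24 h of recovery. Each of the 4 groups held 3 libraries. The design asks what loss of Slc2a5 changes in microglia after an ischaemia-like insult, and what recovery changes in each genotype. Total counts in replicates 1, 2 and 3 were 39283125, 32426683 and 45347118 in WT-OGD and 44142877, 31509859 and 38027592 in KO-OGD. They were 9885259, 15495478 and 12630759 in WT-recovery and 19915479, 13407885 and 18002226 in KO-recovery. Recovery libraries were thus shallower in both genotypes. The share of counts from the mitochondrial genome was 4.20% to 5.75% in the OGD libraries. It was 18.4%, 7.35% and 8.0% in WT-recovery replicates 1, 2 and 3, and 8.23%, 10.5% and 4.72% in those of KO-recovery.

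Slc2a5 (ENSMUSG00000028976.10, chromosome 4, 150119283 to 150144169, GRCm38) was a low transcript in every library. Its counts were 45, 40 and 58 in WT-OGD replicates 1 to 3, and 17, 4 and 17 in those of KO-OGD. After OGD the level was 1.16 ± 0.0564 CPM in WT and 0.333 ± 0.177 CPM in KO (SD, n = 3), with all 3 KO libraries below all 3 WT libraries. The log2 fold change was -1.75, SE 0.38, adjusted p = 0.0108 by edgeR's quasi-likelihood test. The call was lost without WT-OGD replicate 2 (adjusted p = 0.0520) or replicate 3 (adjusted p = 0.0690), and over all alternatives the adjusted p ran from 3.38e-04 to 0.974, the last with an astrocyte-marker covariate. After recovery the counts were 1, 2 and 0 in WT and 1, 0 and 0 in KO, at or under the floor of 3 counts per group, so no genotype fold can be given there. The labels of the recovery libraries could not be checked by this gene. The recovery over OGD ratio was 0.0667 in WT (95% counting interval 0.0136 to 0.199) and 0.0563 in KO (0.00139 to 0.333). Gene-level counts do not show which part of the gene was deleted.

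Transcripts of the sex chromosomes differed between groups of libraries that were all labelled male. Xist, the X-linked RNA that silences an X chromosome in female cells, had counts of 6528, 5111 and 7656 in WT-OGD, 10232, 7040 and 8922 in KO-OGD, 0, 3 and 0 in WT-recovery, and 7139, 4101 and 5828 in KO-recovery. The KO over WT ratio after recovery was 4305 (95% counting interval 1473 to 20877), and after OGD the log2 fold change was 0.61 (adjusted p = 0.00168). Tsix overlaps Xist on the other strand and was counted alike, so both are uncertain as separate genes. The Y-linked genes, chosen after their values were seen, had reads in every library. Ddx3y had 1895, 1339 and 1825 counts in WT-OGD, 908, 888 and 871 in KO-OGD, 392, 814 and 642 in WT-recovery, and 297, 181 and 402 in KO-recovery. After OGD, Kdm5d, Eif2s3y, Uty and Ddx3y were lower in KO by log2 fold changes of -0.72, -0.66, -0.78 and -0.73 (adjusted p = 0.0378, 1.23e-04, 0.00200 and 0.00472). After recovery they were lower by -1.40, -1.35, -1.33 and -1.47.

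**Figure D1:**
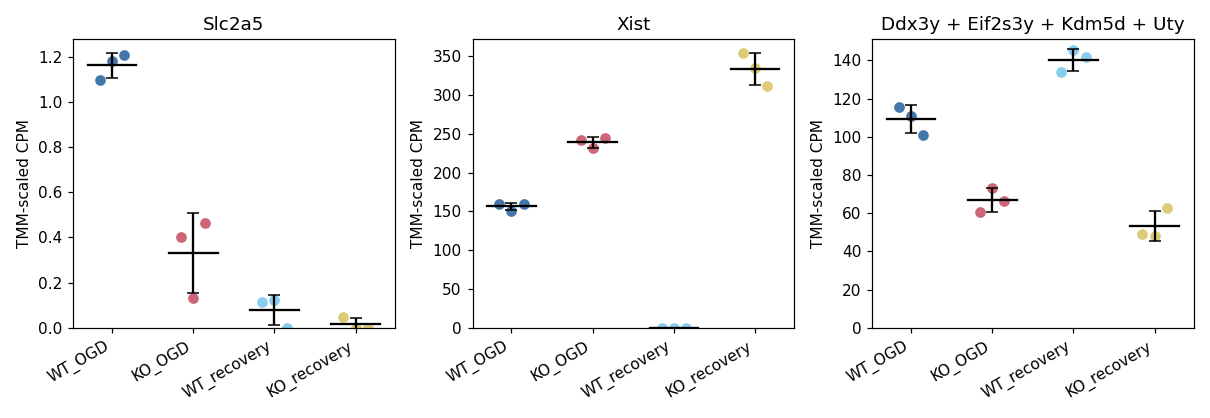
TMM-scaled CPM (vertical axes) of Slc2a5, of Xist and of the sum of Ddx3y, Eif2s3y, Kdm5d and Uty in each library, by group (WT_OGD, KO_OGD, WT_recovery, KO_recovery); points are libraries, lines are group means and bars are SD. Xist was high in 9 libraries and at 0 to 3 counts in those of WT_recovery, while Y-linked reads were present in all 12.

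After OGD, the KO libraries differed from those of WT mainly by lower transcripts. Rab6b, which encodes a small GTPase, fell from 7.33 ± 0.502 to 0.530 ± 0.110 CPM (SD, n = 3; log2 fold change -3.78, SE 0.26, adjusted p = 4.03e-07). The membrane glycoprotein gene Pdpn fell from 15.3 ± 3.70 to 1.30 ± 0.477 CPM (log2 fold change -3.55, SE 0.25, adjusted p = 2.21e-06). Aldh1a1, a retinaldehyde dehydrogenase gene, fell from 6.49 ± 1.78 to 0.633 ± 0.329 CPM (log2 fold change -3.35, SE 0.32, adjusted p = 2.24e-05). Among rises, the chemokine receptor genes Ccr1l1 and Ccr2 rose by log2 fold changes of 7.84 and 2.37 (adjusted p = 4.66e-10 and 3.05e-06). Ccr1l1 (chromosome 9, 123977243 to 123978408, GRCm38) went from 0.527 ± 0.176 to 125 ± 9.35 CPM. Emilin2, encoding an extracellular matrix protein, rose by 1.55 and Clstn1, a calsyntenin gene, by 1.52 (adjusted p = 4.03e-07 and 2.29e-05). Eno1b and Pcna-ps2, intronless copies of genes for the glycolytic enzyme enolase and the replication clamp, rose by 3.38 and 3.10. Eno1 fell by 0.59 and Pcna did not pass at 0.05. Ccr1l1, Eno1b (which also overlaps AC150274.2) and Pcna-ps2 have close copies, Ccr2 has related receptors, and their split of reads is uncertain. In each gene named as called here and in the other simple contrasts, all 3 libraries of one group lay beyond all 3 of the other.

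By edgeR's quasi-likelihood test 1411 genes were called after OGD, 182 higher and 1229 lower in KO, of which 45 and 879 changed at least 2-fold. DESeq2 called 506 higher and 1270 lower. With edgeR, 555 and 1364 were called with only the 6 libraries compared, 477 and 1343 without the 2 libraries of highest mitochondrial share, and 518 and 1630 without a low-count filter, so the share of rises depends on the settings. The count was 524 without WT-OGD replicate 3, 760 without WT-OGD replicate 2, 747 without KO-OGD replicate 1 and 863 without KO-OGD replicate 2. It was 2148 without a low-count filter, 676 with libraries thinned to equal depth, and 98 with the astrocyte-marker level as a covariate, which also ended the call of Slc2a5 and turned the direction of Olig1 and of the HIF and astrocyte list tests. Of the genes named here or below, that covariate also ended the call and moved the value by over 1.5 times for Aldh1a1 (to -1.42), Aqp4 (-0.58), Sox9 (-0.36), Gfap (-0.48), Fosb (-0.49), Map2 (-1.04), Rtn1 (-0.02), Olig1 (0.13), Olig2 (-0.28) and Eda2r (-0.66). It ended the call with a value within 1.5 times for Eno1, Pfkm, Gpr34, Btg2, Fos, Il18, Marco, Stmn1 and Mcm5. Calls that held moved to -2.28 for Pdpn, 1.70 for Ccr2, -1.35 for Axl and -2.73 for Chil3. Thinning and the covariate were chosen after seeing the data. Groups did not overlap in 30.4% of genes, against 10% by chance.

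Genes of cell division were lower in KO after OGD. Of 25 proliferation genes 22 fell and none rose (24 and 0 adjusted over the list alone), among them the mitotic kinase gene Bub1 (-1.59, adjusted p = 1.27e-05), the tubulin regulator gene Stmn1 (-0.95, 4.38e-05) and the replication helicase gene Mcm5 (-1.09, 6.55e-05). The list had a median log2 fold change -0.95, camera adjusted p = 7.83e-38, adjusted p = 0.0583 with an estimated correlation. With the astrocyte covariate 1 fell, with a median of -0.52, and the list call held (camera adjusted p = 2.66e-04). Of 22 immediate early and heat shock genes 5 fell, including Fosb (-1.59, 5.29e-04), Btg2 (-0.63) and Fos (-1.24). None rose (6 lower and 1 higher adjusted over the list alone), and the list had a median log2 fold change -0.10, camera adjusted p = 0.0199, adjusted p = 0.371 with an estimated correlation. The call on this list was lost without WT-OGD replicate 1 (adjusted p = 0.0576) or KO-OGD replicate 2 (0.111), and with the astrocyte covariate (0.627), where none fell and Fosb stood at -0.49 (adjusted p = 0.663). Of 11 astrocyte markers 10 fell (11 adjusted over the list alone), led by the water channel gene Aqp4 (-2.18, 6.74e-04), Sox9 (-1.89) and the filament gene Gfap (-2.26, 0.00309). The astrocyte list had a median log2 fold change -1.89, camera adjusted p = 5.07e-13, adjusted p = 0.140 with an estimated correlation. The number that fell was 6 without WT-OGD replicate 2 or KO-OGD replicate 2, 4 without WT-OGD replicate 3 and 5 without KO-OGD replicate 1. Of 12 neuron markers 4 fell (5 adjusted over the list alone), including the cytoskeletal gene Map2 (-1.94) and Rtn1 (-1.75). The neuron list had a median of -1.26 (camera adjusted p = 1.49e-04, 0.140 with an estimated correlation). The summed level of astrocyte markers was 193 ± 36.1 CPM in WT-OGD and 77.4 ± 15.3 CPM in KO-OGD. That of proliferation genes was 528 ± 42.3 and 342 ± 29.6 CPM (SD, n = 3), so both moved together with genotype. The call of Sox9 ended when libraries were thinned to equal depth. Stmn1 and Map2 overlap other annotated genes, and their values are uncertain.

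**Figure D2:**
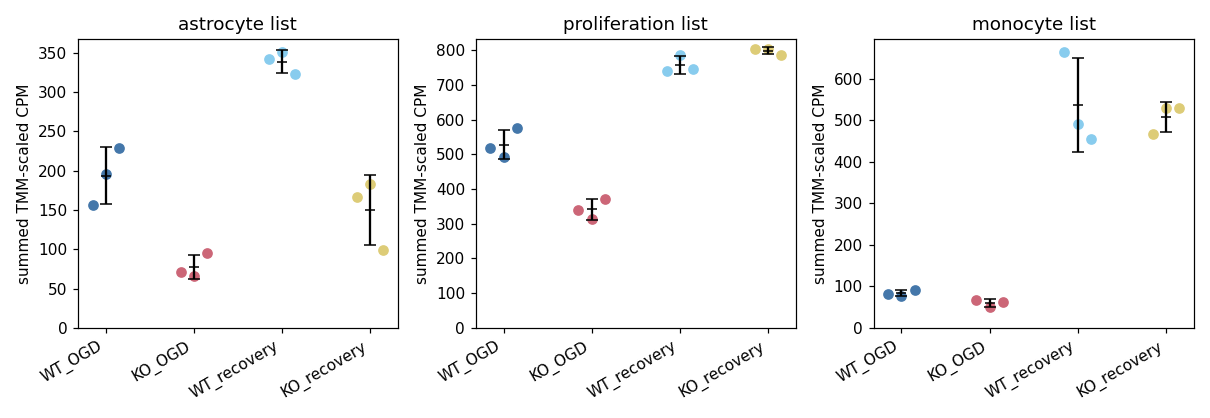
Summed TMM-scaled CPM (vertical axes) of the astrocyte, proliferation and monocyte lists in each library, by group (WT_OGD, KO_OGD, WT_recovery, KO_recovery); points are libraries, lines are group means and bars are SD. Astrocyte markers were lower in KO in both states, proliferation genes were lowest in KO_OGD, and monocyte markers were high after recovery in both genotypes.

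Single genes of the microglia and macrophage lists changed in KO after OGD, in both directions. The scavenger receptor gene Marco fell from 208 ± 17.1 to 73.8 ± 16.6 CPM (log2 fold change -1.49, SE 0.16, adjusted p = 1.17e-04). The receptor kinase gene Axl fell from 233 ± 10.1 to 141 ± 10.3 CPM (-0.72, SE 0.15, adjusted p = 0.00806). These are 2 of 3 falls among 35 phagocytosis genes, of which none rose, or 4 without KO-recovery replicate 3. The chitinase-like gene Chil3 fell from 15.1 ± 1.02 to 3.42 ± 0.242 CPM (-2.13, SE 0.19, adjusted p = 1.62e-05). In the monocyte list 1 of 8 genes rose, Ccr2, and 3 fell (the fall of 3 became 1 without WT-OGD replicate 2 or 3 or KO-OGD replicate 2), with a median log2 fold change -0.52, camera adjusted p = 0.447. In the homeostatic list of 19, 1 gene rose and 5 fell, among them Gpr34 (-1.14), but only 1 to 3 fell without any one OGD library or KO-recovery replicate 1. Of 25 cytokine genes 1 rose and 3 fell, including Il18 (-0.74), with 1 falling without WT-OGD replicate 2 or 3 or any one KO-OGD library. The calls of Gpr34 and Il18 ended when libraries were thinned to equal depth. The repair list had 2 falls of 15, led by Chil3, and the p53 list 1 of 18, Eda2r (-1.63). Camera adjusted p was 0.567 for phagocytosis (median 0.07, mean -0.03, test upward), 0.700 for homeostatic (0.11, -0.09, upward), 0.700 for cytokine, 0.494 for repair and 0.819 for p53 genes (0.05, -0.07, upward). Adjusted over the list alone, higher and lower counts were 0 and 3, 2 and 7, 2 and 3, 1 and 2, and 0 and 1 in the same order, and 1 and 3 for monocytes.

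Few glycolysis and fructose genes changed in KO after OGD. Of 19 glycolysis genes 1 rose and 2 fell (5 and 2 adjusted over the list alone), the falls being Eno1 (-0.59, adjusted p = 0.00135) and Pfkm (-0.66), and Pfkl stood at 0.31 without passing (list median log2 fold change 0.19, camera adjusted p = 0.0649). Of 7 fructose genes 1 fell, Slc2a5 itself (0 and 1 adjusted over the list alone; median log2 fold change -0.03, camera adjusted p = 0.494). No member passed, over all genes or adjusted over the list alone, among 20 HIF targets, 18 antigen presentation genes and 19 cholesterol synthesis genes. HIF targets had a median log2 fold change 0.15, camera adjusted p = 0.0437, adjusted p = 0.795 with an estimated correlation. Antigen presentation genes had a median of 0.18 (camera adjusted p = 0.0199, 0.795 with an estimated correlation). Cholesterol synthesis genes had one of 0.14 (camera adjusted p = 0.0356, 0.831 with an estimated correlation). Each of these list tests passed in the upward direction. The disease-associated list of 24 had 1 fall (0 and 1 adjusted over the list alone) and an upward test (median log2 fold change 0.22, camera adjusted p = 0.0106, adjusted p = 0.795 with an estimated correlation). Values that did not pass were 0.34 for Hilpda, 0.29 for H2-K1, 0.31 for Fdft1 and 0.41 for Igf1. The HIF call was lost without WT-OGD replicate 3 (adjusted p = 0.131) or KO-OGD replicate 2 (0.648), the antigen call without KO-OGD replicate 1 (0.164), and the cholesterol call without WT-OGD replicate 2 (0.177) or KO-OGD replicate 2 (0.994) or with the astrocyte covariate (0.481). Across the remaining lists camera adjusted p was 0.849 for mitochondrially encoded subunits (median -0.04, test upward), 0.0723 for nuclear ones, 0.232 for interferon, 0.954 for integrated stress, 0.150 for NRF2, and 0.819 for lipid genes. For markers of other cells it was 0.898 for oligodendrocyte (median 0.17, mean -0.18, test downward), 0.757 for endothelial, 0.494 for border macrophage, 0.732 for neutrophil (median -0.16, mean 0.05, test downward) and 0.700 for lymphocyte genes. In these 11, members called were 1 lower for the integrated stress and lipid lists each, and 1 higher and 2 lower (Olig1 -2.36 and Olig2 -2.13, the latter -2.99 without KO-OGD replicate 3 and -3.04 with thinned libraries) for the oligodendrocyte list, and adjusted over the list alone the lipid list had 3 falls and the oligodendrocyte list 2 rises. The call of Pfkm ended when libraries were thinned to equal depth. Pfkm, Olig1 and Fdft1 overlap other genes and are uncertain.

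After recovery, the KO libraries had far lower transcripts of the class II antigen presentation genes H2-Eb1, H2-Aa and H2-Ab1 than those of WT. Which cells made these transcripts was not tested. WT-recovery alone held almost no Xist, so genotype and sex were not separated in this contrast. H2-Eb1 fell from 45.3 ± 14.9 to 1.16 ± 0.248 CPM (SD, n = 3; log2 fold change -5.26, SE 0.34, adjusted p = 1.74e-06). H2-Aa fell from 84.3 ± 19.4 to 4.09 ± 1.34 CPM (-4.36, SE 0.34, adjusted p = 1.56e-05), and H2-Ab1 from 60.5 ± 11.6 to 3.56 ± 0.497 CPM (-4.07, SE 0.25, adjusted p = 8.19e-07). Cd74, their invariant chain, fell from 709.6 ± 89.8 to 137 ± 3.35 CPM (-2.37, SE 0.16, adjusted p = 4.19e-07). Pdpn fell from 40.7 ± 10.0 to 1.47 ± 0.0774 CPM (-4.76, SE 0.28, adjusted p = 2.16e-07). The chemokine gene Ccl22 fell from 39.7 ± 22.7 to 2.02 ± 0.645 CPM (-4.24, SE 0.51, adjusted p = 3.47e-04). Arg1, encoding arginase 1, rose from 12.3 ± 2.21 to 69.7 ± 3.64 CPM (2.50, SE 0.15, adjusted p = 7.69e-08). Saa3, an acute phase gene, rose from 60.8 ± 10.7 to 296 ± 108 CPM (2.28, SE 0.22, adjusted p = 4.29e-05). Eno1b and Pcna-ps2 rose again, by 3.66 and 3.48, and Eno1 fell by 0.61, with the same uncertainty of shared reads. Cd74 overlaps Mir5107 and H2 genes resemble one another, so their values are uncertain.

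By the naming rule, the largest rise after Xist and the overlapping Tsix was that of Lum, a connective tissue proteoglycan gene, with a KO over WT count ratio of 230 (95% counting interval 41 to 9115). Lum lay at 8.68, 0.735 and 6.42 CPM in KO-recovery replicates 1 to 3. The same libraries had 37.6, 0.980 and 36.4 CPM of the skeletal muscle actin gene Acta1, 20.9, 1.63 and 18.7 CPM of the cartilage collagen gene Col2a1, and 53.3, 1.55 and 47.2 CPM of the fetal growth factor gene Igf2. Replicates 1 and 3 thus stood apart in these genes from replicate 2, and for Lum from WT-recovery (1 count). Whether RNA of other tissues caused this was not tested. In all, 4175 genes were called, 1909 higher and 2266 lower in KO, with 391 and 1161 changed at least 2-fold, and the count was 2653 without WT-recovery replicate 2, 2756 with only the 6 libraries compared and 2188 with the astrocyte covariate. Of the genes named for this contrast, that covariate ended the call and moved the value by over 1.5 times for Acta1 (from 6.89 to 6.09), S100b (to -1.09), Slc1a2 (-0.75), Pf4 (1.19), Map2 (-1.29), Mmp9 (1.44), Olig1 (-1.03) and Olig2 (-1.31). It ended the call with a value within 1.5 times for Ccl22, Lum, Igf2, Col2a1, Hmgcs1, Clec7a, Flt1, Akr1b3, Il18, Nr1h3, Mmp8, Bcl2 and C3. Calls that held moved to -3.60 for Pdpn, 1.29 for Saa3, 3.04 for Irf7, 3.62 for Ms4a4c, -1.19 for Rtn1, -1.84 for Me1 and -1.84 for Gsr. Without the 2 libraries of highest mitochondrial share Ccl22 stood at -3.52 and Mmp9 at 3.02. Groups did not overlap in 33.5% of genes, against 10% by chance.

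Interferon-stimulated genes were higher in KO after recovery: 8 of 25 rose and none fell (12 and 0 adjusted over the list alone), such as the antiviral GTPase gene Mx1 (1.12, adjusted p = 8.57e-04), Oas1a (0.64) and Irf7 (2.02). The list had a median log2 fold change 0.54, camera adjusted p = 0.00109, adjusted p = 0.894 with an estimated correlation, and 4 rose without WT-recovery replicate 3. Of 10 border macrophage genes 3 rose (3 adjusted over the list alone; 5 without KO-recovery replicate 3), Siglec1 (0.92, 2.02e-05), Pf4 (1.97, 4.70e-05) and F13a1 (2.37). Their list median was 0.67 (camera adjusted p = 0.00109, 0.368 with an estimated correlation). Of 18 antigen presentation genes 8 rose and 5 fell (9 and 5 adjusted over the list alone), the falls including the class II genes above, and 5 rose without WT-recovery replicate 3. Its median log2 fold change was 0.23, its mean -0.72 and its test downward (camera adjusted p = 0.182). Of 35 phagocytosis genes 7 rose and 4 fell (10 and 4 adjusted over the list alone). There were 11 rises without KO-recovery replicate 3 and 2 falls without KO-recovery replicate 1. Marco stood at -2.46 (adjusted p = 8.96e-07) and the complement gene C3 at 0.49 (list median log2 fold change 0.13, camera adjusted p = 0.681). Of 24 disease-associated genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; 4 rose without WT-recovery replicate 2 or 3), with the lysozyme gene Lyz2 at -0.61 and the lectin gene Clec7a at 0.49 (list median log2 fold change 0.17, camera adjusted p = 0.0743). F13a1 and Irf7 overlap other genes and are uncertain.

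In the other immune lists after recovery, 4 of 25 cytokine genes rose and 6 fell (6 and 8 adjusted over the list alone; 7 rose without WT-recovery replicate 1), with Il18 at -1.22 and Ccl5 at 1.90 (list median log2 fold change -0.20, camera adjusted p = 0.905). Of 19 homeostatic genes 4 rose and 4 fell (5 and 5 adjusted over the list alone), with Fcrls at 1.01 and Gpr34 at -2.00 (list median log2 fold change -0.07, camera adjusted p = 0.781), and 2 rose without WT-recovery replicate 2 or 3 or KO-recovery replicate 1 or 2. Of 15 repair genes 4 rose, led by Arg1, and 2 fell, led by Ccl22 (4 and 2 adjusted over the list alone; camera adjusted p = 0.353, median 0.01, mean -0.02, test upward), and 2 rose without those same 4 libraries, each in turn. Neutrophil genes rose in 3 of 5 cases, among them the protease genes Mmp8 (0.77) and Mmp9 (2.38) (3 and 1 adjusted over the list alone; list median log2 fold change 0.84, camera adjusted p = 0.105). Monocyte genes rose in 2 of 8 cases, among them Ms4a4c (1.97) (2 and 0 adjusted over the list alone; camera adjusted p = 0.652, median -0.02, mean 0.40, test upward). No lymphocyte gene of 3 passed (median log2 fold change -0.09, camera adjusted p = 0.905). Ms4a4c overlaps another gene and is uncertain.

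Of 11 astrocyte markers 8 were lower in KO after recovery (8 adjusted over the list alone), including S100b (-2.54, adjusted p = 4.24e-05), the glutamate transporter gene Slc1a2 (-2.26) and Aldoc (-0.60). The astrocyte list had a median log2 fold change -1.57, camera adjusted p = 4.28e-05, adjusted p = 0.368 with an estimated correlation. Their summed level was 339 ± 14.3 CPM in WT-recovery and 149.5 ± 44.5 CPM in KO-recovery (SD, n = 3). Of 12 neuron markers 4 fell (1 and 4 adjusted over the list alone), led by Rtn1 (-2.72) and Map2 (-2.13). Neuron markers had a median log2 fold change -0.51, camera adjusted p = 0.0153, adjusted p = 0.368 with an estimated correlation, a call lost without KO-recovery replicate 2 (adjusted p = 0.0691). Of 12 oligodendrocyte lineage genes 3 fell (0 and 6 adjusted over the list alone; 5 without WT-recovery replicate 1), led by Olig2 (-3.01) and Olig1 (-3.24). The oligodendrocyte list had a median log2 fold change -0.97, camera adjusted p = 0.0310, adjusted p = 0.368 with an estimated correlation and 0.494 with the astrocyte covariate, which also turned the direction of the astrocyte list test (0.889). Endothelial and mural genes had 2 rises and 1 fall of 7 (5 and 1 adjusted over the list alone; 5 rises without KO-recovery replicate 2), with the growth factor receptor gene Flt1 at 0.82 (list median log2 fold change 1.92, camera adjusted p = 0.182). Slc1a2, Map2 and Olig1 overlap other genes and are uncertain.

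Nuclear respiratory chain genes had 4 falls of 27 in KO after recovery, led by Ndufa4 (-0.71, adjusted p = 3.28e-05) and Cox5a (-0.59), and none rose (0 and 4 adjusted over the list alone). These nuclear genes had a median log2 fold change -0.11, camera adjusted p = 0.160. NRF2 targets had 4 falls of 16, led by Me1 (-1.20) and Gsr (-0.92) (0 and 4 adjusted over the list alone). The NRF2 list had a median log2 fold change -0.26, camera adjusted p = 0.0743, and there were 2 falls without KO-recovery replicate 1 and 10 without replicate 3. Integrated stress genes had 1 rise, Calr (0.70), and 6 falls of 24, led by the amino acid transporter gene Slc7a5 (-1.28) and the serine synthesis gene Phgdh (-0.84) (1 and 6 adjusted over the list alone). That list had a median log2 fold change -0.00, camera adjusted p = 0.738, and there were 2 falls without WT-recovery replicate 3, 3 without KO-recovery replicate 1, and 4 rises without KO-OGD replicate 2. Cholesterol synthesis had 3 falls of 19, led by Hmgcs1 (-0.84) (0 and 3 adjusted over the list alone; median log2 fold change -0.18, camera adjusted p = 0.182). Glycolysis genes had 1 rise and 4 falls of 19 (1 and 4 adjusted over the list alone; Eno1 -0.61, Hk3 0.71; median log2 fold change 0.13, camera adjusted p = 0.843). There were 2 rises and 3 falls among 20 HIF targets (2 and 3 adjusted over the list alone; Ndrg1 0.84, Mxi1 -0.43; camera adjusted p = 0.747, median 0.09, mean -0.03, test upward; 1 fall without WT-recovery replicate 2). Lipid genes had 2 rises and 2 falls of 20 (3 and 3 adjusted over the list alone; Nr1h3 -0.76; camera adjusted p = 0.843, median 0.09, mean -0.01). Immediate early and heat shock genes had 1 rise and 2 falls of 22 (1 and 2 adjusted over the list alone; Ier2 -1.05; median log2 fold change -0.14, camera adjusted p = 0.517). Proliferation genes had 2 rises and 2 falls of 25 (2 and 2 adjusted over the list alone; Mcm5 0.59; median log2 fold change 0.11, camera adjusted p = 0.653). The p53 list had 3 rises and 4 falls of 18 (4 and 4 adjusted over the list alone; Bcl2 0.81; median log2 fold change -0.11, camera adjusted p = 0.843). It had 1 rise and 1 fall without WT-recovery replicate 2 and 2 falls without WT-recovery replicate 3 or KO-recovery replicate 2. Fructose handling had 1 fall of 7, Akr1b3 (-0.37) (0 and 1 adjusted over the list alone; median log2 fold change -0.03, camera adjusted p = 0.676). No mitochondrially encoded gene of 13 passed (median log2 fold change -0.51, camera adjusted p = 0.756), and that median turned to 0.22 without WT-recovery replicate 1, the library with the 18.4% mitochondrial share. Cox5a, Me1, Hmgcs1, Hk3, Ndrg1, Mxi1, Bcl2 and Nr1h3 overlap other genes, and their values are uncertain.

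Recovery changed 10701 of 18842 genes tested in WT and 11113 in KO, and integrated stress genes, HIF targets and immediate early genes were lower after it. Recovery coincided with the loss of Xist counts in WT. In KO Xist rose (log2 fold change 0.48) and of the Y-linked genes only Ddx3y was called (-0.54). Sex and recovery were thus not separated in either. Asns, which makes asparagine under amino acid shortage, fell from 169 ± 8.31 to 10.5 ± 1.59 CPM in WT and from 159.7 ± 22.9 to 12.2 ± 1.48 CPM in KO (SD, n = 3; log2 fold changes -4.03 and -3.72, adjusted p = 1.47e-11 and 1.60e-11). Integrated stress genes fell in 19 and 17 of 24 cases and rose in 2 and 2, with Mthfd2 at -3.42 and -3.38. Camera adjusted p was 7.66e-19 and 2.98e-18 (adjusted p = 0.125 and 0.0904 with an estimated correlation). HIF targets fell in 14 and 16 of 20 cases and rose in 2 and 1, with the demethylase gene Kdm3a at -1.74 and -1.84 and Ddit4 at -2.15 and -3.12. Their camera adjusted p was 8.03e-05 and 1.90e-05 (adjusted p = 0.151 and 0.159 with an estimated correlation). Immediate early and heat shock genes fell in 14 and 13 of 22 cases and rose in 4 and 6, with Junb at -2.29 and -2.91, and camera adjusted p = 5.38e-04 and 0.00417 (adjusted p = 0.125 and 0.167 with an estimated correlation). Trib3, a stress-induced pseudokinase gene, was among the largest falls in WT at -6.20, and Il1rapl1, a receptor accessory gene, was the largest fall in KO at -8.07. In WT 5068 genes were higher and 5633 lower, in KO 5527 higher and 5586 lower, and groups did not overlap in 67.1% and 61.2% of genes, against 10% by chance. Adjusted over the list alone, higher and lower counts in WT and in KO were 2, 19, 2 and 17 for integrated stress, 2, 14, 1 and 16 for HIF targets, and 6, 14, 7 and 13 for immediate early genes. Junb overlaps Prdx2 and is uncertain.

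Interferon-stimulated and monocyte genes rose with recovery in both genotypes. The chemokine gene Ccl2 rose from 7.35 ± 1.65 to 179.7 ± 39.2 CPM in WT and from 7.98 ± 0.175 to 422 ± 83.5 CPM in KO (SD, n = 3; log2 fold changes 4.60 and 5.73). Interferon-stimulated genes rose in 20 and 20 of 25 cases, none fell, and the RNA sensor gene Ddx58 stood at 1.65 and 2.03 (camera adjusted p = 1.31e-06 and 3.87e-09; adjusted p = 0.337 and 0.230 with an estimated correlation). Cytokine genes rose in 14 and 13 of 25 cases and fell in 3 and 6 (camera adjusted p = 1.42e-04 and 3.80e-04; adjusted p = 0.163 and 0.206 with an estimated correlation). The fall of 3 in WT became 6 without KO-OGD replicate 2, that of 6 in KO became 3 without KO-OGD replicate 1 or 3 and 2 without KO-recovery replicate 3, and the KO list call was lost without KO-OGD replicate 2 (adjusted p = 0.0634). Antigen presentation genes rose in 16 and 11 of 18 cases and fell in 1 and 4, with Cd80 at 2.30 and 2.88 (camera adjusted p = 9.37e-08 and 0.00305; adjusted p = 0.135 and 0.332 with an estimated correlation). All 8 monocyte genes rose in both, such as S100a4 (3.47 and 3.71), with camera adjusted p = 2.00e-09 and 1.27e-10 (0.00443 and 0.00306 with an estimated correlation, so both held). Phagocytosis genes rose in 18 and 21 of 35 cases and fell in 4 and 4, with the nucleotide receptor gene P2ry6 at 2.47 and 2.42 (camera adjusted p = 1.09e-04 and 2.11e-04; adjusted p = 0.151 and 0.192 with an estimated correlation). Border macrophage genes rose in 8 and 8 of 10 cases and fell in 1 and 0, with Pf4 at 4.36 and 6.16 (camera adjusted p = 6.48e-04 and 7.33e-06; adjusted p = 0.135 and 0.0897 with an estimated correlation). Neutrophil genes rose in 3 and 3 of 5 cases and fell in 2 and 1, with Mmp8 at 4.09 and 5.30 (camera adjusted p = 0.0181 and 0.00256; adjusted p = 0.151 and 0.0897 with an estimated correlation). Lymphocyte genes rose in 1 and fell in 2 of 3 cases in both (camera adjusted p = 0.668 and 0.437), and their median of -1.41 in WT changed sign when libraries were thinned. Adjusted over the list alone, the counts of these lists differed only for cytokine falls in KO (7), antigen presentation rises in KO (12) and border macrophage rises in WT and KO (9 and 9). S100a4 overlaps another gene and is uncertain.

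Proliferation genes rose with recovery in 13 of 25 cases in WT and 24 in KO, and none fell, with the helicase genes Mcm3 at 0.85 and 1.35 and Mcm6 at 0.91 and 1.55 (camera adjusted p = 5.23e-04 and 1.56e-16; adjusted p = 0.434 and 0.0897 with an estimated correlation). Homeostatic genes went both ways, with 10 and 8 rises and 6 and 8 falls of 19, the transcription factor gene Sall1 falling by -2.19 and -2.32 and Selplg rising by 1.38 and 1.21 (camera adjusted p = 0.149 and 0.340). Disease-associated genes had 7 and 8 rises and 6 and 6 falls of 24, with Lpl at 0.83 and 1.26 (camera adjusted p = 0.385 and 0.340). Repair genes had 9 and 6 rises and 3 and 3 falls of 15, with Arg1 at 3.75 and 5.71 (camera adjusted p = 0.0424 and 0.0284; adjusted p = 0.163 and 0.206 with an estimated correlation). The WT call was lost without WT-OGD replicate 2 (0.0565) or 3 (0.0566), KO-OGD replicate 2 (0.0521), WT-recovery replicate 1 (0.0654) or KO-recovery replicate 1 (0.102) or 2 (0.0579), and the KO call without KO-OGD replicate 2 (0.0686) or KO-recovery replicate 1 (0.0515) or 2 (0.0606). Adjusted over the list alone, WT and KO rises were 11 and 9 for homeostatic genes, 10 and 7 for repair, 13 and 24 for proliferation and 7 and 8 for disease-associated genes. When mitochondrial genes and the 50 most abundant genes were removed, the disease-associated counts became 3 and 4 rises and 2 falls in each, since members left the table.

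Respiratory chain genes were higher with recovery in WT, by calls that an estimated correlation ended, and glycolysis genes went both ways. Glycolysis genes had 7 rises and 9 falls of 19 in WT and 7 and 9 in KO, with the hexokinase gene Hk2 at -1.65 and -2.11 and Pfkfb3 at -1.32 and -1.43 (camera adjusted p = 0.278 and 0.111; 4 rises in WT without WT-OGD replicate 2 or WT-recovery replicate 1). Nuclear respiratory chain genes had 18 and 12 rises and 2 and 2 falls of 27, with Cox7b at 1.07 and 1.02 (camera adjusted p = 0.00826 and 0.340; in WT adjusted p = 0.518 with an estimated correlation; 7 rises in KO without KO-recovery replicate 2). Mitochondrially encoded genes had 8 and 6 rises of 13 and no falls, beside a mitochondrial share that was above that of every OGD library in 5 of 6 recovery libraries (camera adjusted p = 0.0424 and 0.111; in WT adjusted p = 0.750 with an estimated correlation and 0.141 with the astrocyte covariate). In WT, 5 rose without WT-OGD replicate 1 or 3 or WT-recovery replicate 1, and the list call was lost without WT-OGD replicate 1 (0.0582) or 3 (0.0822), KO-OGD replicate 1 (0.0516) or 2 (0.0717), WT-recovery replicate 1 (0.0692) or KO-recovery replicate 3 (0.0518). NRF2 targets had 4 and 3 rises and 6 and 11 falls of 16, with Sqstm1 at -2.42 and -2.43 (camera adjusted p = 0.829 and 0.0690; in WT median 0.10, mean -0.15, test downward). Cholesterol genes had 7 and 3 rises and 3 and 7 falls of 19, with Insig1 at -1.16 and -1.43 (camera adjusted p = 0.468 and 0.418; 5 rises in KO without KO-OGD replicate 2). Lipid genes had 6 and 8 rises and 4 and 4 falls of 20 (camera adjusted p = 0.716 and 0.499; in KO median -0.01, mean 0.22). The p53 list had 8 and 5 rises and 5 and 4 falls of 18, with the apoptosis gene Bbc3 at -2.40 and -2.44 (camera adjusted p = 0.892 and 0.895; medians 0.10 and 0.06, means -0.02 and -0.04). Fructose genes had 1 rise, Akr1b3 (0.77 and 0.42), and 3 falls of 7 in each (camera adjusted p = 0.788 and 0.629). Adjusted over the list alone, the counts of these lists differed only in rises, which were 12 and 6 for mitochondrially encoded genes, 11 for nuclear ones in KO, 6 for cholesterol in WT and 4 for p53 in KO. Sqstm1 overlaps Mrnip and is uncertain.

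Oligodendrocyte lineage markers were also higher after recovery in both genotypes. They rose in 12 of 12 cases in WT and 10 in KO, among them the myelin genes Mag (1.5 and 1.54) and Mbp (1.38 and 1.13), with camera adjusted p = 3.06e-07 and 2.11e-04 (0.0294 and 0.0395 with an estimated correlation, so both held). Neuron markers rose in 10 and 10 of 12 cases and fell in 1 and 0. Their camera adjusted p was 0.0112 and 0.0258 (adjusted p = 0.163 and 0.286 with an estimated correlation). Neuron markers had summed levels of 38.9 ± 8.05 CPM in WT-OGD, 14.6 ± 4.14 in KO-OGD, 121 ± 18.1 in WT-recovery and 44.0 ± 5.99 in KO-recovery (SD, n = 3). Astrocyte markers rose in 4 and 5 of 11 cases and fell in 2 and 0, with Aldoc at 0.99 and 0.84 (camera adjusted p = 0.207 and 0.175; 7 rose in WT without KO-recovery replicate 3). Endothelial and mural genes rose in 1 and 4 of 7 cases, with Flt1 at 3.29 and 4.01 (camera adjusted p = 0.170 and 0.0258; in KO adjusted p = 0.332 with an estimated correlation, and 0.0550 without KO-OGD replicate 2). Adjusted over the list alone the counts were the same in these 4 lists, except 5 astrocyte rises in WT. Myh8, a developmental muscle myosin gene at 0 in KO-OGD, was at least 412-fold higher in KO-recovery, with 12.7, 0.572 and 16.9 CPM in replicates 1 to 3, and the imprinted RNA H19 lay at 102, 2.78 and 86.5 CPM there.

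**Figure D3:**
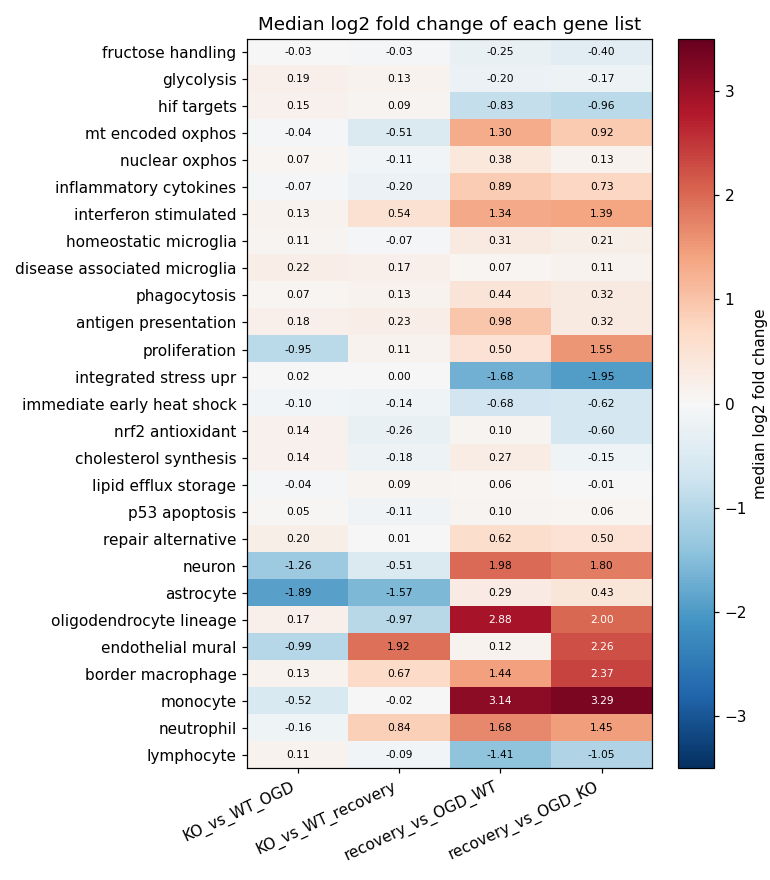
Median log2 fold change (cell number and colour) of the tested members of each of the 27 gene lists (vertical axis) in the 4 simple contrasts (horizontal axis: KO_vs_WT_OGD and KO_vs_WT_recovery compare genotypes within a state, recovery_vs_OGD_WT and recovery_vs_OGD_KO compare states within a genotype). The astrocyte list had the lowest median in both genotype contrasts (-1.89 and -1.57), and the monocyte list the highest in both recovery contrasts (3.14 and 3.29).

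The recovery change differed between genotypes for Ccr1l1, H2-Eb1, Ccl22, Cd74 and most proliferation genes. In the interaction, where a negative value means a smaller rise or larger fall with recovery in KO, Ccr1l1 had -6.81 (adjusted p = 3.13e-08), as it rose with recovery in WT (6.99) and stood at 0.18 in KO. H2-Eb1 had -5.30 (7.15e-05), Ccl22 -5.06 (0.00689) and Cd74 -2.69 (1.50e-05). Proliferation genes had higher interaction values in 19 of 25 cases and lower ones in none (23 and 0 adjusted over the list alone), with Mcm5 at 1.68 (6.69e-05) and Bub1 at 1.73 (3.40e-04). Their list had a median log2 fold change 0.85, camera adjusted p = 3.26e-24, adjusted p = 0.205 with an estimated correlation. That number was 11 without WT-OGD replicate 3, WT-recovery replicate 3 or KO-recovery replicate 1. Border macrophage genes had 3 higher values of 10 (3 and 0 adjusted over the list alone), including Siglec1 (1.21) and Pf4 (1.81). Their list median was 0.93 (camera adjusted p = 0.00462, 0.347 with an estimated correlation). NRF2 targets had 2 lower values of 16 (0 and 2 adjusted over the list alone), led by Me1 (-1.02). There were 9 without KO-recovery replicate 3, and 1 without WT-OGD replicate 1 or 3, KO-OGD replicate 1, WT-recovery replicate 2 or KO-recovery replicate 1. The NRF2 list had a median log2 fold change -0.37, camera adjusted p = 8.70e-04, adjusted p = 0.347 with an estimated correlation. Antigen presentation genes had 1 higher (4 without KO-recovery replicate 3, none without 8 other libraries, each in turn) and 4 lower of 18 (2 and 6 adjusted over the list alone; median 0.10, mean -0.83, test downward, camera adjusted p = 7.00e-05, adjusted p = 0.347 with an estimated correlation). In all 989 genes were called, 544 higher and 445 lower. The count was 479, 583 and 568 without WT-OGD replicates 3, 1 and 2, 599 and 629 without KO-OGD replicates 1 and 3, 565 without WT-recovery replicate 2, and 566 and 1770 without KO-recovery replicates 1 and 3. It was 1517 with DESeq2, 1980 without a low-count filter and 594 with thinned libraries. Ccr1l1, Cd74, Me1 and the H2 genes share or overlap other genes and are uncertain.

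Genotype differences in both states overlapped. Among 18842 genes, 93 were higher in KO in both states (18.4 expected of independent lists, Fisher's exact p = 1.89e-44), 582 were lower in both (148 expected, p = 8.00e-228), and 47 were called in opposite directions. Averaged over both states, 4179 genes differed by genotype (1692 higher, 2487 lower), among them Pdpn (-4.16, and -2.94 with the astrocyte covariate), Rab6b (-3.27), Eno1b (3.52) and Pcna-ps2 (3.29), with the last 2 uncertain as above. Averaged over genotypes, 13003 genes differed by recovery (6366 higher, 6637 lower), with C77080 (-6.98), which overlaps Yars and is uncertain, and Il1rapl1 (-6.83) as the largest falls. Recovery changes in WT and in KO correlated across genes with r = 0.805 and rho = 0.807, and genotype changes in OGD and in recovery with r = 0.402 and rho = 0.318. The averaged genotype and recovery changes had r = -0.189 and rho = -0.0853 across genes, and rho was 0.0640 over genes of at least 10 CPM. Genes are not independent replicates, so these values only describe the libraries.

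Genes near Slc2a5 on chromosome 4 differed more often by genotype than genes elsewhere. Within 10 Mb of Slc2a5, 82 of 213 genes were called in the averaged genotype contrast (38.5%), against 3880 of 17874 elsewhere (21.7%), with an odds ratio of 2.26 (two-sided Fisher's exact p = 3.75e-08). After OGD 40 of 213 were called (18.8% against 7.12%), with an odds ratio of 3.02 (Fisher's exact p = 2.26e-08). After recovery 76 of 213 were, with an odds ratio of 2.0 (Fisher's exact p = 3.58e-06). Pdpn (143267431 to 143299564) and Eno1 (150236721 to 150248879) lie in this window on GRCm38 and were among the genes left out. Eno1b lies on chromosome 18 (48045335 to 48048412) and Pcna-ps2 on chromosome 19 (9283380 to 9284160).

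**Figure D4:**
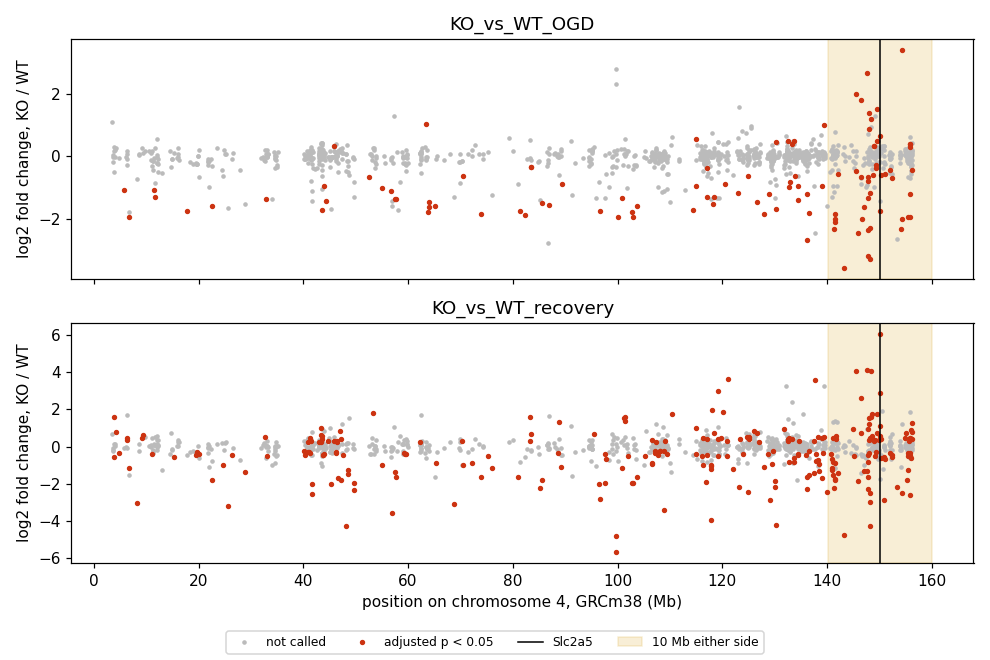
Log2 fold change of KO over WT (vertical axes) against position on chromosome 4 in Mb, GRCm38 (horizontal axes), after OGD and after recovery; points are genes, red where adjusted p was below 0.05 and grey elsewhere, the line marks Slc2a5 and the shading 10 Mb on either side. Called genes made up 18.8% of the shaded window after OGD against 7.12% of genes elsewhere, with Slc2a5, Eno1 and the genes of the largest changes left out of these shares.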

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

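All tests of explanations in this part were chosen only after the result was seen. The results given here are those where the change with recovery differed between KO and WT by the interaction test of edgeR, which compares the 2 genotypes' effects directly. It called 989 genes. Whether chance can be excluded for this count stays open. Among 100 splits of the samples 2 gave as many calls, the real one included, and the highest other split gave 1252. That split and 6 more kept the genotype labels of the recovery libraries and mixed those of the OGD libraries, with 246 to 1252 calls. A genotype difference after recovery alone thus yields such counts, and this comparison of splits is no test of an interaction.

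The largest negative interaction values were -6.81 for Ccr1l1, -6.05 for Sox10, -5.30 for H2-Eb1, -5.06 for Ccl22 and -4.58 for the neurotrophin receptor gene Ngfr, each a smaller rise or larger fall with recovery in KO. The call of Sox10, a transcription factor gene of the oligodendrocyte and Schwann lineages, was lost without WT-OGD replicate 3 (adjusted p = 0.0536) or KO-OGD replicate 2 (0.347), and with libraries thinned to equal depth (-4.04, adjusted p = 0.349). Its fitted value is no bound, since it had almost no counts after OGD, and it was -8.14 without WT-OGD replicate 1, -5.46 without WT-OGD replicate 3, -6.70 without KO-OGD replicate 1 and -3.86 without KO-OGD replicate 2. Ngfr was -3.90 without KO-OGD replicate 2, and Ccl22 was -4.37 without the 2 libraries of highest mitochondrial share. Ccr1l1 and H2-Eb1 have related genes that may share their reads, and their values without any one library stayed within 1.5-fold of these.

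The largest positive values were 11.38 for Xist and 11.38 for the overlapping Tsix, 6.61 for Col2a1, 5.81 for Ckm and 3.39 for Casq1. Ckm and Casq1 encode a creatine kinase and a calcium-binding protein of skeletal muscle. The Xist value is no bound, as WT-recovery held 3 counts, and it was 15.55 without WT-recovery replicate 2 and 10.78 without replicate 3. The Col2a1 call was lost without any one OGD library (adjusted p from 0.0866 to 0.122), WT-recovery replicate 2 (0.121) or 3 (0.101) or KO-recovery replicate 1 (0.0819) or 3 (0.0615), and its value was 8.35 without WT-recovery replicate 1 and 8.83 without the 2 libraries of highest mitochondrial share. Thinning to equal depth (0.0980) and the astrocyte covariate (0.0719) also ended it. The Ckm call was lost without any one OGD library (0.0577 to 0.104), any one WT-recovery library (0.0727 to 0.0900) or KO-recovery replicate 1 (0.0674), and with the astrocyte covariate (0.0657). The Casq1 call was lost without WT-OGD replicate 2 (0.0636) or 3 (0.0619), KO-OGD replicate 1 (0.0795) or 2 (0.0569), any one WT-recovery library (0.0561 to 0.107), or KO-recovery replicate 1 (0.0881) or 3 (0.0676). Ckm was at 6.79, 0.57 and 8.73 CPM in KO-recovery replicates 1 to 3, and it overlaps A930016O22Rik and is uncertain.

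Among gene lists the interaction test passed for 8, with median log2 values of -0.19 for nuclear respiratory chain, 0.31 for interferon-stimulated, 0.10 for antigen presentation, 0.85 for proliferation, -0.37 for NRF2, -0.30 for cholesterol synthesis, 0.93 for border macrophage and 0.95 for neutrophil genes. Of the 4 not described in the main text, nuclear respiratory chain genes had 3 of 27 lower (0 and 4 adjusted over the list alone), with Ndufa4 at -0.78; the camera adjusted p was 0.00139, and adjusted p = 0.677 with an estimated correlation. That number was 1 without WT-OGD replicate 1 or 2, KO-OGD replicate 1, WT-recovery replicate 2 or KO-recovery replicate 1, and 5 without KO-OGD replicate 2. Interferon-stimulated genes had 1 of 25 higher, Mx1 (1.40) (3 without WT-recovery replicate 2 and 6 without KO-recovery replicate 3; 3 and 0 adjusted over the list alone; camera adjusted p = 0.0228, adjusted p = 0.977 with an estimated correlation), and the list call was lost without KO-OGD replicate 2 (0.0918), WT-recovery replicate 3 (0.327) or KO-recovery replicate 2 (0.250). Cholesterol synthesis had 1 of 19 lower (none without any one library but KO-OGD replicates 1 and 2 and WT-recovery replicate 1; 0 and 1 adjusted over the list alone; camera adjusted p = 0.00122, adjusted p = 0.677 with an estimated correlation), lost without KO-recovery replicate 3 (0.0748). Neutrophil genes had 1 of 5 higher, Mmp8 (1.21) (2 without KO-recovery replicate 3; 2 and 0 adjusted over the list alone; camera adjusted p = 0.0479, adjusted p = 0.347 with an estimated correlation), lost without WT-OGD replicate 1 (0.0908), KO-OGD replicate 2 (0.0918) or 3 (0.0864), WT-recovery replicate 2 (0.110) or 3 (0.125), or KO-recovery replicate 2 (0.111) or 3 (0.0501).

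The sex-linked transcripts were weighed against technical explanations. Single libraries exchanged between WT-recovery and another group are excluded, since the lowest Xist count outside WT-recovery was 4101 and the highest inside it 3. Cells of both sexes in different proportions may be present, since the 4 Y-linked genes, read in every library, had a median log2 fold change of -1.37 where the KO-recovery libraries alone held Xist, and all 4 were called lower. Whether sex is the source of the recovery genotype calls stays open: 3879 genes were still called without X, Y and flanking genes, but autosomal genes can differ by sex and no fit within libraries of 1 sex could be made. All recovery calls and the interaction calls stay open in the same way, since only WT-recovery lacked Xist, and Xist rose with recovery in KO (0.48). After OGD, Xist was higher in KO (0.61) and all 4 Y-linked genes were called lower (-0.66 to -0.78). The genotype calls after OGD, averaged and shared by both states thus stay open too. So does a biological effect of the genotype, which was not separated from sex.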

How the results depend on the processing

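Tests chosen only after seeing the data were thinning to equal depth, the astrocyte covariate, removal of X, Y and flanking genes, and removal of the 2 libraries of highest mitochondrial share; all others were planned. Of 14878 values of 696 gene results under alternatives 14177 kept direction and side of the threshold, 692 lost the call and 9 reversed. Of 1080 values of 72 list results 968 kept both, 107 lost the call and 5 reversed. Of 158 counts of calls 128 stayed within 1.5 times. Small counts of called list members were unsteady: 33 of 51 counts of 1 and 28 of 44 counts of 2 moved by over 1.5 times when some single library was left out, and 36 of 109 counts of 0 rose. The cause of the changes below was not tested, except where stated. Depth limits the low genes of the recovery libraries most.

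Against a fold of 1.5, a stricter test by construction, calls were 408 and 989 for genotype after OGD and after recovery, 4582 and 4905 for recovery in WT and in KO, 136 for the interaction, and 905 and 5555 for averaged genotype and recovery. Without a low-count filter there were 2148 for genotype after OGD and 1980 for the interaction. Thinning, which leaves fewer counts, gave 676 and 594 for these, and DESeq2 gave 1517 for the interaction. With only the libraries compared, 1919 and 2756 genes were called for genotype after OGD and after recovery, and 11144 and 9591 for recovery in WT and in KO. RLE factors, removal of mitochondrial and abundant genes, removal of X, Y and flanking genes (1274, 3879, 10156, 10574, 880, 3866 and 12364 calls, in the order above) and removal of the 2 libraries of highest mitochondrial share (1820, 3520, 10414, 11034, 1123, 4014 and 12935) kept all 7 counts within 1.5 times. At an unadjusted p of 0.01, 827 genes were shared by both genotype contrasts against 675. Over genes of at least 10 CPM the correlation of averaged changes moved from -0.189 to -0.0547, and Spearman's from -0.0853 to 0.0640.

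With the astrocyte covariate calls were 98 for genotype after OGD, 2188 after recovery and 900 averaged. Slc2a5 went to -0.12 (adjusted p = 0.974; 3.38e-04 to 0.974 over its alternatives), so the covariate also takes up genotype. Log2 fold changes reversed to 0.27 for Slc1a2, -0.00573 for Hk2 and 0.13 for Olig1 after OGD, 0.0701 for Dgat1 after recovery, and 0.0926 for Acta2, 0.0607 for Aldh18a1, 0.20 for Scd1, 0.14 for Vcan and 0.0515 for Hbegf averaged. List tests reversed with adjusted p = 0.694 for HIF targets and 0.832 for astrocyte after OGD, 0.889 for astrocyte after recovery, and 0.963 for both proliferation and astrocyte genes averaged. List calls were gained too. After OGD these were mitochondrially encoded (up, adjusted p = 0.0161), interferon (up, 4.29e-04), integrated stress (up, 0.00619) and NRF2 genes (down, 0.00364). After recovery they were proliferation (up, 9.17e-04) and NRF2 (down, 2.12e-07), and averaged integrated stress (up, 0.0471) and NRF2 (down, 6.19e-06).

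With 1 library left out, calls ranged from 524 (without WT-OGD replicate 3) to 1742 (KO-recovery replicate 3) for genotype after OGD, 2653 (WT-recovery replicate 2) to 5279 (KO-recovery replicate 3) after recovery, 9512 (WT-OGD replicate 2) to 11452 (KO-recovery replicate 3) for recovery in WT, 9979 (KO-recovery replicate 1) to 11717 (WT-recovery replicate 1) in KO, 479 (WT-OGD replicate 3) to 1770 (KO-recovery replicate 3) for the interaction, 2985 (WT-recovery replicate 2) to 5497 (KO-recovery replicate 3) for averaged genotype and 12390 (WT-OGD replicate 2) to 13387 (KO-recovery replicate 3) for averaged recovery. Slc2a5 ranged from -2.03 (KO-OGD replicate 3) to -1.40 (KO-OGD replicate 2).

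The replicate numbers shared across groups did not pair the samples: 1 of 18 same-numbered pairs had a correlation of deviations over 0.1 (range -0.228 to 0.156, against -0.244 to 0.233 for other pairs). With the number as a block calls were 1179, 3641, 10269, 10681, 657, 3648 and 12707 in the order above, and all 72 list calls held. An estimated correlation ended 66 of 72 list calls. The averaged and interaction contrasts cannot be fitted with only the libraries compared, and genes left out of a table have no value under that alternative. The test against a fold of 1.5 was run for counts alone.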

Other observations

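Tests of explanations chosen only after the result was seen were those on reads shared by Eno1 and Eno1b, on the share of microglia, on the astrocyte covariate, and on all splits of the samples but that for the overlap of calls. The second astrocyte list was chosen after the fall of the first list was seen. Several more single genes recovered differently in both genotypes. The chemokine gene Ccl17 went from 1.24 ± 0.458 to 49.7 ± 6.80 CPM in WT and from 1.82 ± 0.410 to 3.14 ± 2.50 CPM in KO (SD, n = 3; interaction -4.46, adjusted p = 0.00303; -5.34 without KO-recovery replicate 3), and the endothelin receptor gene Ednrb from 42.1 ± 2.45 to 77.1 ± 19.5 and from 73.6 ± 25.5 to 12 ± 3.7 CPM (-3.51, 0.00162). Saa3 had an interaction of 2.36 (0.00309), Arg1 1.96 (0.00109) and the Fc receptor-like gene Fcrls 1.5 (7.33e-05). Lyz2 had -0.84 (0.00260).

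Averaged over both states, list tests of genotype passed for interferon-stimulated genes (9 of 25 higher, camera adjusted p = 0.00546; adjusted p = 0.999 with an estimated correlation; 3 without KO-OGD replicate 1, WT-recovery replicate 3 or KO-recovery replicate 2, 4 without WT-OGD replicate 1 or KO-recovery replicate 1, and 5 without WT-OGD replicate 3, KO-OGD replicate 3 or WT-recovery replicate 1) and neuron markers (4 of 12 lower, 1.03e-04; adjusted p = 0.223 with an estimated correlation), among others. Cx3cr1, the reporter locus and a microglial receptor gene chosen after its values were seen, had recovery changes of -0.53 in WT and -0.33 in KO. The share of counts from ribosomal RNA loci was 1.21% ± 0.230 in WT-OGD, 2.61% ± 0.888 in KO-OGD, 0.499% ± 0.302 in WT-recovery and 1.05% ± 0.750 in KO-recovery (SD, n = 3).

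Genes near the targeted locus differed by genotype more often than others. A segment around Slc2a5 from another strain, carried along with the deletion, may account for part of this, since the odds ratio within 10 Mb was 2.26 with the named genes left out. A difference of WT-OGD from the other groups around Cx3cr1, where Ccr1l1 and Ccr2 lie, stays open, since the odds ratio of interaction calls was 1.08 (8 of 145 genes against 924 of 18017, Fisher's exact p = 0.849). Reads shared between Eno1 and its copy Eno1b could contribute to that pair, since Eno1 was lower by -0.59 after OGD where Eno1b was higher, and the counting of shared reads is not given in the sources used here.

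Astrocyte markers were lower in KO in both states although the cells had been sorted as microglia. Fewer astrocytes, or less of their RNA, in the KO libraries may be the source, since a second astrocyte list had a median log2 fold change of -1.54 after OGD (12 of 22 tested genes lower) and -1.86 after recovery (15 lower), with 2 genes whose values had been seen left out. A higher share of microglia in the KO libraries stays open. Against a higher share, the astrocyte and oligodendrocyte lists differed in median by -2.07 after OGD (permutation p = 0.00292 over 100000 resamples), and summed oligodendrocyte levels were 161 and 156 CPM in WT and KO. The permutation moved genes between lists, and genes are not independent replicates, so its p does not measure the spread between samples. A sum can be carried by few abundant members, and whether microglia make some of them was not tested. After recovery endothelial and mural genes had a median of 1.92. Yet several oligodendrocyte genes were near the floor after OGD, Olig1 (-2.36) and Olig2 (-2.13) fell like the astrocyte markers, and neuron markers fell too (median -1.26). Whether astrocyte content is the source of the genotype calls after OGD stays open: 98 genes were called with the astrocyte covariate, but the deleted gene lost its call as well, so that test decides nothing. A change in astrocyte genes caused by the genotype itself was not tested.

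For the simple contrasts the 10 splits of 6 samples are too few for a share under 0.05. In each, 1 split, the real one, gave as many calls, with 1411, 4175, 10701 and 11113 in the real split and 0, 254, 0 and 0 in the highest other. The averaged genotype count was 4179 against 1469 in the highest other of 100 splits, and the averaged recovery count 13003 against 3473. In each, 1 split, the real one, was as large, so the real labels gave more calls than any other split drawn. Most other splits called 0 genes, as mixing real groups widens the spread within them. Since the libraries may be technical repeats, chance between animals or cultures cannot be excluded. For the 675 calls shared by both genotype contrasts, against 10 in the highest other split, 1 split was as large, but the other splits of the OGD libraries alone called 0 genes and so left almost none to share, and this comparison decides nothing. Chance cannot be excluded for the correlation of averaged genotype and recovery changes, -0.189, as 8 of 100 splits were as large and the highest other was -0.231.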
